A study of Mus musculus with 12 samples.

How the data were processed

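RNA of 12 mouse lung samples, 6 controls and 6 with acute lung injury, was extracted with TRIzol, made into libraries with the NEBNext Ultra RNA kit and sequenced on the NovaSeq platform, per the labels' protocols. The authors deposited 1 table of whole-number counts per gene, not normalised, with Ensembl gene IDs, symbols, positions and lengths. The submitters' processing notes name fastp, HISAT2, featureCounts and the build GRCm38 (mm10), without versions, settings or order. Whether counting used strand, and how reads matching several genes were treated, is not given in the sources used here, so counts of close paralogs and of overlapping or antisense genes are uncertain. Of the 157 genes chosen for the text, 3 share at least 20% of their exon bases with another gene (Bcl2a1b 49.1%, Lemd1 37.7%, Hopx 27.2%).

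Samples were grouped by their treatment label, and columns were matched to samples by title. Of the 54532 gene IDs in the table, 54495 were found in the GENCODE M21 annotation of GRCm38, and 98.0% of those had a deposited length equal to the M21 exon union. Only 2.91% of 51094 deposited start positions equalled the GRCm38 start, so the deposited positions were not used and coordinates are those of GENCODE M21, taken by gene ID. The table held 0 lines without a gene ID and 0 columns of other samples. Depth was 15707937 to 19706494 counts per sample. Within groups, counts of every pair of samples differed by more than sampling noise (chi-square per degree of freedom 6.91 to 239 over 30 pairs, genes with at least 20 counts over the pair), so all 12 were treated as separate samples.

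Counts were analysed in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM, and ALI was compared with control by the robust quasi-likelihood F test of edgeR 4.0.16, with no covariate and Benjamini-Hochberg adjustment over 16185 genes. A gene was called at an adjusted p under 0.05, and a separate count required an absolute log2 fold change of at least 1. CPM values use the TMM-scaled library size, and log CPM values a prior count of 2. A fold against a group with no counts uses a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% interval. Both cover counting error only, since counts are pooled over the group and the spread between samples is not used. Reads carry no molecular identifiers, so duplicate reads cannot be told from separate molecules.

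The gene lists, 66 in all with 1099 symbols, of which 1079 matched an ID and 969 distinct genes were tested, the tests and most alternatives were fixed before the data were examined. They cover inflammation and sensing, fluid and barrier function, stress, metabolism, lung and immune cell types, tissues that dissection can carry over, and library quality. Some lists share members, so their results are not independent. Lists of at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, which called 39 lists by direction. Fry was also run without regard to direction. That asks whether members changed at all, not whether they changed more than other genes. The score of a list is the mean log2 CPM of its members in a sample. Scores, shares of the library and other values per sample were compared by two-sided exact permutation of 6 against 6.

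Named genes follow a fixed rule. It takes the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between groups, up to 4 called members with the smallest p of each main list and up to 2 of each other list, and a set given whatever the result (Il1b, Il6, Tnf, Cxcl1, Tlr4, Nlrp3, Sftpc, Scnn1a, Aqp5, Nfat5, Mki67). Some genes the rule takes are not reported here. Dbp and Arntl, the marker transcripts of single samples, and the members left out of a list score (Slc6a12, Lpl, Sftpd, Bpifb1) were chosen after their values were seen.

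The pipeline was tested on counts simulated from the real means and library sizes for the comparison of ALI with control, with 16010 genes and 50 genes changed at each size. It recovered 38% of genes changed 1.5-fold, 54% at 2-fold, 88% at 3-fold and 96% at 4-fold. Of 150 calls 6 (4%) fell on unchanged genes. A shifted list had an adjusted p of 9.8e-21 and 0 of 60 unshifted lists were called. The simulated genes varied independently, so this does not test lists whose members move together. Oxidative phosphorylation genes, for example, had an estimated correlation of 0.991 in the data. Far fewer genes were changed than the 36.6% called in the data, so the recovered shares need not carry over.

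Alternatives were DESeq2 1.42.0, limma-voom with sample weights, DESeq2 size factors, upper-quartile factors, library size alone, no filter, at least 1 CPM in 6 samples, removal of mitochondrial, haemoglobin and ribosomal protein genes, the replicate number as a block, 1 surrogate variable (sva 3.50.0), each sample left out in turn, an adjusted p under 0.01 and the estimated correlation. Leaving out control 5 and ALI 2 together, an adipose score as a covariate and protein-coding genes only were added after seeing the data.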

Results

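Lung RNA was profiled by bulk RNA sequencing in 12 mouse samples, 6 controls and 6 from animals with acute lung injury (ALI), a condition in which inflammation and leakage of the air-blood barrier impair gas exchange. The series design concerns drowning in seawater as the cause of the injury, and its title ties lung injury to a disturbed gut flora and an inflammatory response. The labels give neither the dose of the exposure nor the time between injury and collection. Each sample held between 15707937 and 19706494 counts. The total was 17003503 ± 995462 (SD, n = 6) in controls and 17629930 ± 1099871 (SD, n = 6) in ALI, a difference within the spread between samples (two-sided exact permutation p = 0.34). Of 54532 genes in the table, 30737 had at least 1 count in some sample and 16185 had enough counts to be tested. Levels are given as normalised counts scaled to library size (CPM), as mean ± SD over the 6 samples of a group, and changes as log2 fold change, ALI against control, with adjusted p from edgeR. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

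The comparison of ALI with control asks which transcripts of the lung differ once the organ is injured. In injured lungs the lists of acute phase, interstitial macrophage, cell cycle and extracellular matrix genes were higher, and those of capillary endothelium, alveolar type 1 cells and red cells lower. With a correlation estimated per list these higher calls held and the lower ones were lost (adjusted p = 0.109, adjusted p = 0.220 and adjusted p = 0.219). The acute phase protein gene Saa3 rose 188-fold, from 1.75 ± 0.930 to 326 ± 137 CPM. Mki67, a marker of dividing cells, rose 8.60-fold, from 21.9 ± 7.04 to 189 ± 23.3 CPM, and Eln, which encodes elastin, rose 11.5-fold, from 205 ± 53.8 to 2356 ± 443 CPM. Plvap, which encodes a diaphragm protein of endothelial vesicles, fell from 823 ± 106 to 297 ± 36.3 CPM, and Scgb1a1, the secretoglobin of club cells, from 12318 ± 5614 to 2659 ± 987 CPM. Each of these genes was past the threshold in edgeR's test, with all 6 ALI values beyond all 6 control values.

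**Figure D1:**
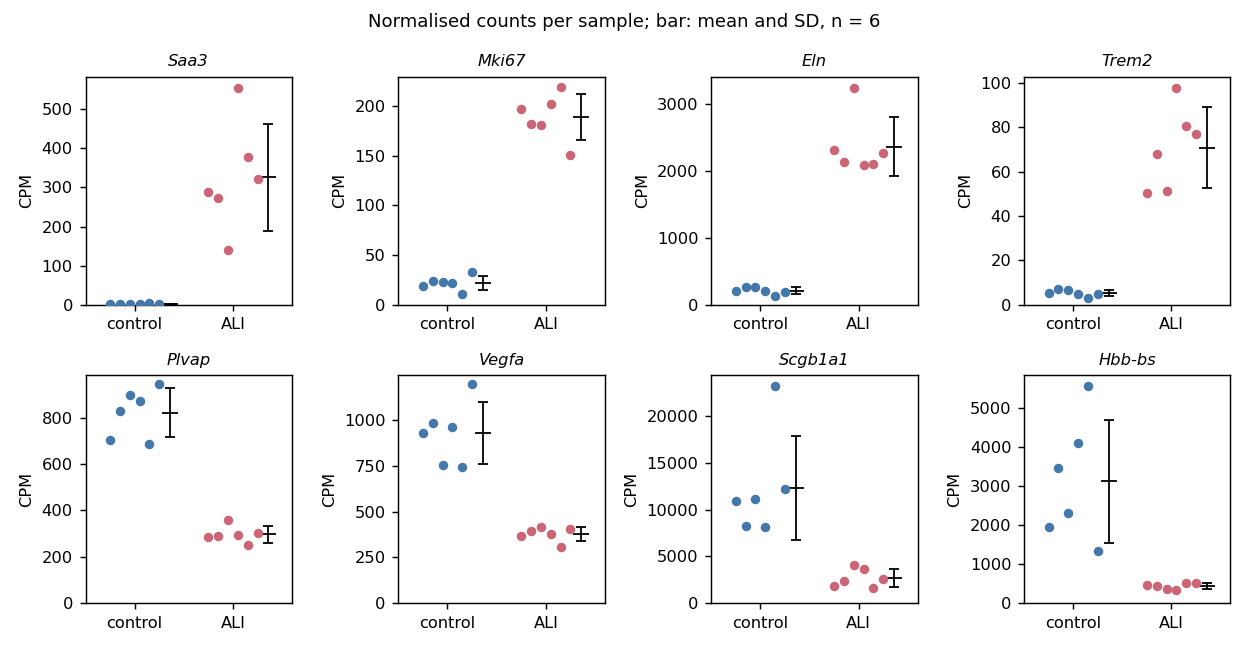
Normalised counts (CPM) of 8 genes in each of the 6 control and 6 ALI samples, with the group mean and SD as a bar beside the points. The ALI samples lie above every control for Saa3, Mki67, Eln and Trem2 and below every control for Plvap, Vegfa, Scgb1a1 and Hbb-bs.

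At an adjusted p under 0.05, 5922 genes (36.6% of those tested) differed, 3062 higher and 2860 lower in ALI. A change of at least 2-fold was met by 1894 of them, 1295 higher and 599 lower. In 2113 genes every ALI value lay above every control value, and in 1335 every ALI value lay below, where chance gives 0.216% of genes, or 35.0. Control 5 held 2858 CPM of Ucp1 and 269 CPM of Adipoq, and ALI 2 held 59.2 CPM of Adipoq, transcripts typical of adipose tissue that were chosen after their values were seen. Without both samples, a choice made after the data were seen, 6825 genes differed (3583 higher, 3242 lower), 1986 of them at least 2-fold (1385 higher, 601 lower). The first principal component held 51.0% of the variance and parted the groups, with controls from -61.1 to -41.4 and ALI samples from 29.4 to 61.7. The second held 20.6% and set control 5 apart, at -91.5. The biological coefficient of variation was 0.257.

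**Figure D2:**
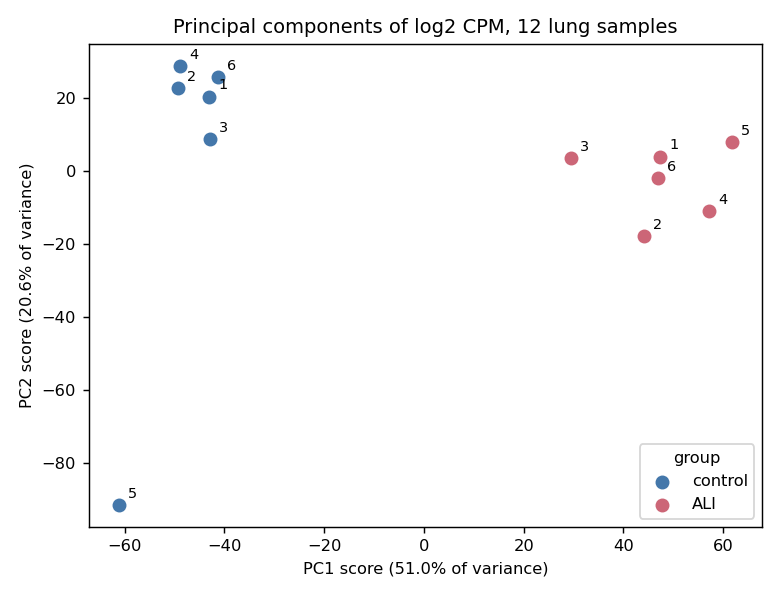
First and second principal component of the log2 CPM values of the 12 samples, in principal component score units, colored by group and numbered by sample. The groups part along the first component, and control 5 lies at -91.5 on the second.

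**Figure D3:**
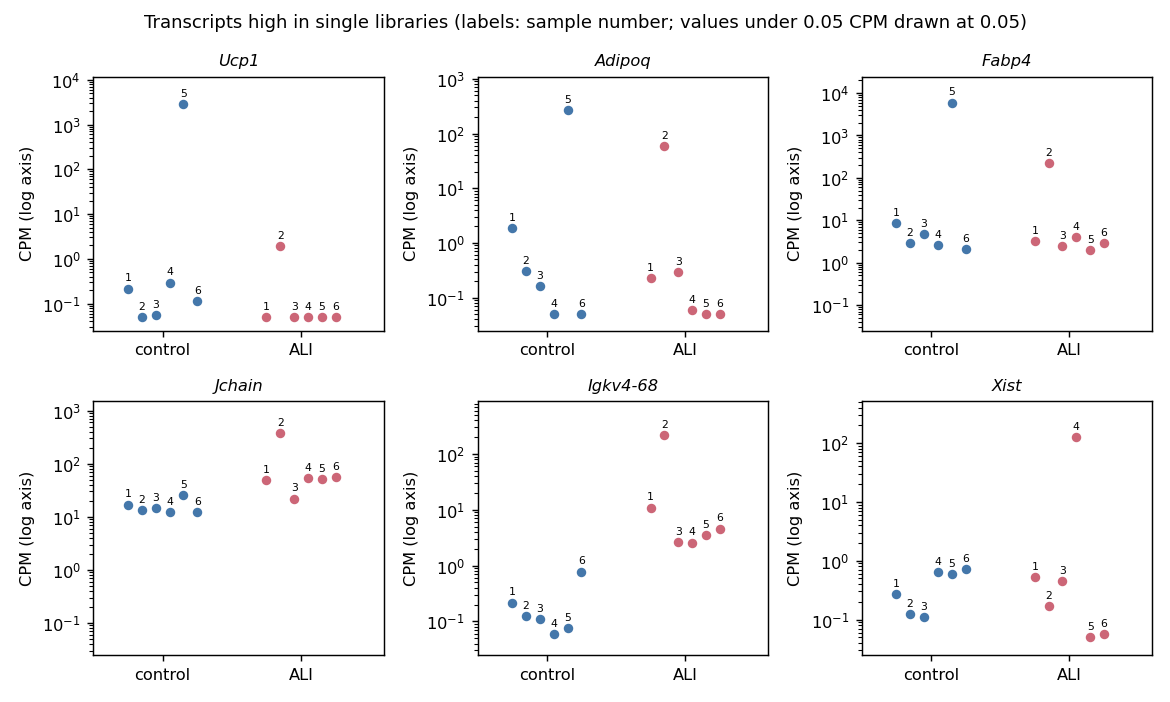
Normalised counts (CPM, log axis) of 6 transcripts in each of the 12 samples, numbered by sample, with values under 0.05 drawn at 0.05. Ucp1 and Adipoq stand high in control 5, Adipoq, Jchain and Igkv4-68 in ALI 2, and Xist in ALI 4.

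**Figure D4:**
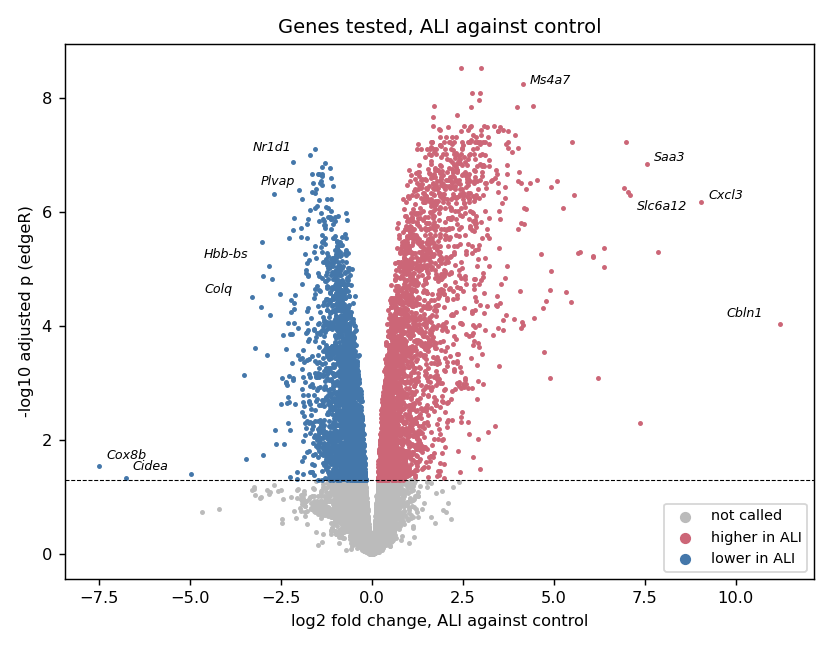
Log2 fold change of each tested gene against the negative log10 of its edgeR adjusted p, with genes past 0.05 colored by direction and the dashed line at 0.05. Of the 16185 genes, 3062 were higher and 2860 lower in ALI.

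Among the 10 largest rises, Cbln1 (ENSMUSG00000031654, chromosome 8, 87468405 to 87472609 on GRCm38, minus strand), known as a secreted synaptic organiser, had no counts in the 6 controls and 17.4 ± 10.3 CPM in ALI, at least 570-fold higher against a floor of 3 counts over the control group. Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600, plus strand), a neutrophil-attracting chemokine, went from 0.0925 ± 0.0886 to 56.4 ± 41.3 CPM, a log2 change of 9.06 ± 0.68 (SE, edgeR adjusted p = 6.64e-07). Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573, plus strand), which makes itaconate in activated macrophages, rose by 7.87 ± 0.73 log2 units to 43.2 ± 30.0 CPM. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand) rose by 7.56 ± 0.46 (adjusted p = 1.43e-07), and Slc6a12 (ENSMUSG00000030109, chromosome 6, 121343076 to 121365775, plus strand), a betaine and GABA transporter, by 7.10 ± 0.59 to 6.44 ± 3.55 CPM, and by 7.75 without control 5. Slc6a12 had only 4 counts over all controls, so the size of its rise is uncertain. Ly6i rose by 7.04 and Gp2 by 6.22, where control 1 alone held the 9 control counts of Gp2; without control 1, Gp2 was at least 192-fold higher against a floor of 3 counts over the other controls. Lemd1 and Saa4 had 3 counts and 1 count over all controls, so only their ratios can be given, 158 (95% counting interval 53.8 to 769) and 209 (37.1 to 8279), whose intervals cover counting error only; without control 2, which held the Saa4 count, Saa4 was at least 58.5-fold higher. The immunoglobulin segment Igkv4-68 rose by 7.38, by 4.33 without ALI 2, which held 218 CPM, and by 8.31 without control 6. Counts of Saa3, Saa4, Ly6i and Igkv4-68 can be shared with close paralogs, and 37.7% of the exon bases of Lemd1 overlap another gene, so their levels are uncertain.

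Among the 10 largest falls, Colq (ENSMUSG00000057606, chromosome 14, 31523082 to 31591343, minus strand), the collagen tail of acetylcholinesterase, fell from 52.0 ± 10.4 to 5.28 ± 3.43 CPM, and Esm1, a proteoglycan of endothelial tip cells, from 21.9 ± 6.48 to 3.42 ± 0.821 CPM. Asgr1 (-3.51), Cyp2a5 (-3.21), Ces1g (-3.01) and Slc5a12 (-2.78) fell too, the Cyp2a5 counts being open to sharing with paralogs. Asgr1 had 13 counts over the ALI group, most of them in ALI 3, and its change was -5.10 without that sample. Fabp3 fell by 3.44, a value set by control 5 at 314 CPM; without that sample it fell by 1.11. The haemoglobin genes Hba-a2, Hba-a1 and Hbb-bs fell, with log2 changes of -3.03, -2.75 and -2.83, and reads of the nearly identical Hba-a1 and Hba-a2 cannot be assigned with certainty. Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096, minus strand) went from 3114 ± 1568 to 439 ± 74.8 CPM.

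Of 66 gene lists fixed in advance, 63 had at least 5 tested members and 32 differed from the other genes by camera with a preset correlation of 0.01, 22 higher and 10 lower. With a correlation estimated per list, 11 lists kept their call, all higher. Among 100 splits of the samples into 6 and 6, 37 called as many lists, the real one included. Splits with unequal numbers of controls on each side keep part of the group difference. This count therefore cannot decide whether the number of lists called is beyond chance. Drawn splits with equal numbers of controls on each side called fewer lists, from 6 to 23, with 0 genes called. Camera at the preset correlation thus calls lists without a group difference, and its adjusted p is to be read beside the estimated correlation and the scores. For single lists, the mean log2 level of the members per sample (the score) differed in 36 of the 66 by a two-sided exact permutation test adjusted over all lists, 27 higher and 9 lower, and in 28 of the 32 lists called by camera all 6 ALI scores lay beyond all 6 control scores (exact p = 0.0021645, the smallest 6 against 6 allows, adjusted p = 0.00476). The plot of list members shows the spread within lists. Genes named below as risen or fallen had no overlap between groups, except Il6, Tnf, Cxcl1, Ifit3b, Scnn1a, Cd8b1, Gzmb, Jchain, Uty, Cox8b and Cidea.

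**Figure D5:**
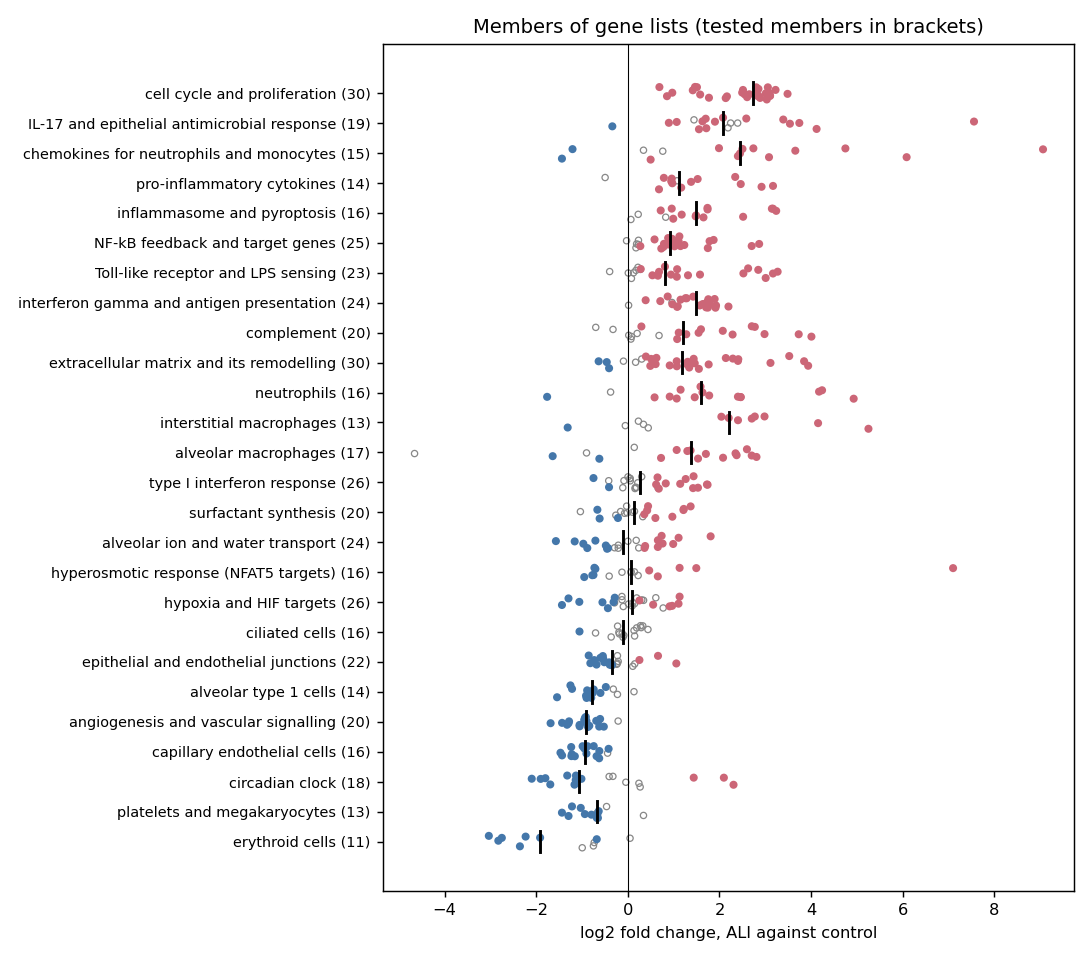
Log2 fold change of each tested member of 26 gene lists, with filled points past an adjusted p of 0.05, open points not past it, and a black bar at the list median. All 30 cell cycle genes lie to the right of 0, and the median of the capillary list is -0.93.

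Inflammatory mediators rose broadly. Of 14 cytokine genes tested, 12 rose and none fell (13 adjusted over the list alone; camera adjusted p = 6.02e-05, and adjusted p = 0.153 with an estimated correlation). Il1b went from 9.07 ± 2.71 to 81.5 ± 47.8 CPM, Il12b rose by 2.92, Il18 by 0.96 and Ptgs2, which makes prostaglandins, by 0.95, while Il6 rose by 2.46 (3.11 without control 5) and Tnf by 2.34. Of 15 chemokines for neutrophils and monocytes, 11 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 4.93e-06, and adjusted p = 0.112 with an estimated correlation). Cxcl5 rose by 6.09, Ccl9 by 3.66, Ccl6 by 2.50 and Cxcl1 by 2.45. Of 11 chemokines for lymphocytes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.000332, and adjusted p = 0.0896 with an estimated correlation), with Ccl8 up by 5.25 and Cxcl16 by 1.48. Of 25 NF-kB feedback and target genes, 20 rose and none fell (21 adjusted over the list alone; camera adjusted p = 1.75e-09, and adjusted p = 0.177 with an estimated correlation), among them Tnip3 (2.87), Tnfaip2 (2.70), Zc3h12a (1.78) and Nfkbie (1.75).

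Genes that sense microbial products and cell damage rose with them. In the Toll-like receptor list 16 of 23 rose and none fell, the same adjusted over the list alone (camera adjusted p = 1.19e-10, and adjusted p = 0.0768 with an estimated correlation). Cd14, the co-receptor for bacterial lipopolysaccharide, rose 9.64-fold, Ticam2 rose by 2.85, Tlr13 by 2.63, Tlr7 by 2.52 and Tlr4 by 1.07. In the inflammasome and pyroptosis list 13 of 16 rose and none fell, the same adjusted over the list alone (camera adjusted p = 5.67e-10), and the call held with an estimated correlation (adjusted p = 0.0490). Mefv rose by 3.24, Naip2 by 3.14, Nlrp3 by 2.52, Naip5 by 1.74 and Casp1 by 1.48, with Naip2 and Naip5 being close paralogs. In the IL-17 and epithelial antimicrobial list 14 of 19 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 6.47e-14, and adjusted p = 0.0124 with an estimated correlation). Lcn2, which binds bacterial siderophores, rose 13.4-fold from 65.1 ± 6.75 to 871 ± 336 CPM, Pigr, the transporter of IgA, rose 10.5-fold and Chil1 rose by 1.71. Of 14 acute phase genes 12 rose and none fell, the same adjusted over the list alone (camera adjusted p = 1.90e-14, and adjusted p = 0.0124 with an estimated correlation).

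Of 24 interferon gamma and antigen presentation genes, 22 rose and none fell, the same adjusted over the list alone (camera adjusted p = 8.15e-20, and adjusted p = 0.0896 with an estimated correlation). H2-K1 rose by 2.20 and H2-D1 by 1.75, related genes whose reads can be shared. The type I interferon list was not called (11 of 26 up, 2 down, the same adjusted over the list alone; camera adjusted p = 0.147). In it Zbp1 rose by 1.74 and Ifi44l by 1.42, while Ifit3b fell by 0.75. Of 20 complement genes 13 rose and none fell, the same adjusted over the list alone (camera adjusted p = 1.52e-16, and adjusted p = 0.00925 with an estimated correlation), with C1qb up 7.91-fold from 16.5 ± 2.10 to 130 ± 23.1 CPM and C1qc up by 2.77. In the coagulation list 9 of 19 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.00221, and adjusted p = 0.0580 with an estimated correlation), F10 by 4.01 and F7 by 2.55 upward. Of 20 anti-inflammatory and resolution genes 14 rose and none fell, the same adjusted over the list alone (camera adjusted p = 5.67e-10, and adjusted p = 0.0380 with an estimated correlation), with Trem2, a lipid receptor of macrophages, up 13.5-fold and Il10ra up 2.83-fold.

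Markers of myeloid cells rose. Of 16 neutrophil genes 14 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.20e-08, and adjusted p = 0.0939 with an estimated correlation), with Clec4d up by 4.93 and Mmp8 by 2.40. Of 12 classical monocyte genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 7.06e-08, and adjusted p = 0.0205 with an estimated correlation), with Ccr2 up by 1.70. Of 17 alveolar macrophage genes 12 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 9.33e-08, and adjusted p = 0.0124 with an estimated correlation), with Itgax up by 2.70 and Atp6v0d2 by 2.37. Of 13 interstitial macrophage genes 8 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 2.92e-16, and adjusted p = 0.00525 with an estimated correlation), with Ms4a7 up 17.8-fold from 2.75 ± 0.417 to 49.2 ± 11.4 CPM. Of 12 dendritic cell genes 7 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.000724, and adjusted p = 0.0380 with an estimated correlation), with Itgae up by 2.22 and Flt3 by 2.17.

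The T cell list was not called (1 of 18 up and 4 down, the same adjusted over the list alone; camera adjusted p = 0.147), with Lef1 down (log2 change -1.35) and Cd8b1 down (-1.01). The NK cell list was not called either (0 of 10 up and 1 down, the same adjusted over the list alone; camera adjusted p = 0.390), and its fallen member was Gzmb (-1.03). Of 14 B cell genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.658 with an estimated correlation), with Ighd at -1.17 and Cd22, the member that rose, at 1.16. The plasma cell list was not called (3 of 11 up, none down, the same adjusted over the list alone; camera adjusted p = 0.511). Its members Jchain and Ighg2b rose by 2.67 and 2.56, and without ALI 2, which held 372 CPM of Jchain, Jchain rose by 1.56. The list of mast cells, basophils and eosinophils was not called (1 of 7 up and 2 down, the same adjusted over the list alone, camera adjusted p = 0.389), with Siglecf at 1.70 and Kit at -0.88. Siglecf is also in the alveolar macrophage list and Kit in the capillary endothelial list, so neither speaks for these cells alone.

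Genes of the cell cycle and of the extracellular matrix rose together with these. All 30 cell cycle genes rose, by a median of 2.73, the same adjusted over the list alone (camera adjusted p = 8.48e-53, and adjusted p = 0.0124 with an estimated correlation). Top2a rose by 3.09, Ccna2 by 3.06, Plk1 by 2.89 and Tpx2 by 2.80. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand) had an adjusted p of 9.97e-08. In the matrix list 24 of 30 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 1.70e-16, and adjusted p = 0.0227 with an estimated correlation). Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323, minus strand) had an adjusted p of 3.15e-08. Ctsk, a collagen-degrading cathepsin, rose 15.3-fold, Mmp12, the macrophage elastase, 14.4-fold, and Spp1 rose by 2.14. Col1a1 and Col1a2 rose by 1.55 and 1.29, yet the fibroblast list, which holds both, was not called (4 of 18 up and 8 down, 5 and 8 adjusted over the list alone; camera adjusted p = 0.350).

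Endothelial genes fell. Of 16 capillary endothelial genes 15 fell and none rose (16 adjusted over the list alone; camera adjusted p = 5.67e-10, and adjusted p = 0.109 with an estimated correlation), by a median log2 change of -0.93. Plvap (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752, minus strand) fell by 1.47 ± 0.11 (SE, edgeR adjusted p = 2.16e-07), and Tbx2 by 0.99. Control 5 had the lowest capillary and alveolar type 1 scores of the controls, and without control 5 and ALI 2 all 16 capillary genes fell. Of 20 angiogenesis genes 19 fell and none rose, the same adjusted over the list alone (camera adjusted p = 9.74e-12, and adjusted p = 0.0580 with an estimated correlation), with Vegfa falling from 929 ± 168 to 378 ± 38.6 CPM and Dll4 at -1.05. The list of arterial, venous and lymphatic endothelium was not called (2 of 15 up and 7 down, 2 and 9 adjusted over the list alone; camera adjusted p = 0.117), Hey1 being at -1.33 and Mgp at 0.90. Of 16 smooth muscle and pericyte genes 10 fell and none rose (12 adjusted over the list alone; camera adjusted p = 0.000501, and adjusted p = 0.0896 with an estimated correlation), with Notch3 at -0.98 and Cox4i2 at -0.77. Of 22 junction genes 12 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.477 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, was at -0.85, Esam at -0.73 and Ocln at -0.51, while Cldn1 rose by 1.06.

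Epithelial lists were tested by cell type. Of 14 alveolar type 1 genes 11 fell and none rose, the same adjusted over the list alone (camera adjusted p = 2.80e-06, and adjusted p = 0.220 with an estimated correlation), with Cav1 at -0.89, Hopx at -0.90 and the water channel Aqp5 at -0.48; 27.2% of the exon bases of Hopx overlap an antisense gene. The alveolar type 2 list was not called (8 of 16 up and 2 down, the same adjusted over the list alone; camera adjusted p = 0.0847), but its score was higher in ALI by 0.29 (exact permutation adjusted p = 0.00922), with 5 of 6 ALI samples above every control, and by 0.23 without Sftpd, its member with the largest change (unadjusted exact p = 0.00649). Its members Sftpd and Muc1 rose by 1.21 and 0.77. Of 14 genes of transitional alveolar cells, an intermediate state seen in regenerating alveoli, 10 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00152, and adjusted p = 0.0768 with an estimated correlation), with Lgals3 up by 1.88, Cdkn1a by 1.06 and Itgb6 by 0.90. The club and goblet cell list was not called (1 of 12 up and 6 down, 2 and 6 adjusted over the list alone; camera adjusted p = 0.125), and its mean log2 change was 0.22 where camera pointed down. In it Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958, minus strand) fell by 2.21 ± 0.30 (SE, edgeR adjusted p = 5.59e-05), from 1.19 ± 0.425% to 0.269 ± 0.103% of the library, and Cbr2 by 1.35. The ciliated list was not called (0 of 16 up and 1 down, Tppp3 at -1.06, the same adjusted over the list alone; camera adjusted p = 0.509). The basal cell list was not called (2 of 5 up and none down, 3 adjusted over the list alone; camera adjusted p = 0.252), but its score was higher by 1.15 (exact permutation adjusted p = 0.0126), and by 0.82 without Bpifb1, its member with the largest change (unadjusted exact p = 0.0021645), with Aqp3 at 1.81 and Trp63 at 1.47. Of 4 submucosal gland genes, too few to test as a list, 3 rose and none fell (4 adjusted over the list alone), with Ltf, which encodes the antimicrobial lactoferrin, up by 3.54 and Dmbt1, with 2 counts over all controls, both in control 3, at a ratio of 93.4 (95% counting interval 25.5 to 777), or at least 51.0-fold higher without control 3.

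Lists on fluid handling and osmotic stress went both ways. Camera tests for a shift in 1 direction, so a list it does not call can still hold many changed genes. By fry without regard to direction the transport, hyperosmotic and surfactant lists passed (adjusted p = 2.01e-09, 8.98e-10 and 2.78e-10). Most lists passed that test, and 36.6% of all tested genes changed. The alveolar ion and water transport list was not called (9 of 24 up and 8 down, the same adjusted over the list alone; camera adjusted p = 0.708). The sodium channel subunits Scnn1b and Scnn1g fell by 0.89 and 0.97. Scnn1a fell by 0.45 (edgeR adjusted p = 0.0207), a call lost without control 4 and without control 6, where its change was -0.39. Fxyd5, a regulator of the sodium pump, rose by 1.11. The hyperosmotic list was not called (5 of 16 up and 5 down, 6 and 6 adjusted over the list alone; camera adjusted p = 0.944). Its score was higher in ALI by 0.30 (exact permutation adjusted p = 0.00476), carried by Slc6a12: without that gene, a check chosen after the data were seen, the score changed by -0.035 (unadjusted exact permutation p = 0.251). Slc6a12 and the glucose transporter Slc2a1 (1.13) rose and Cryab and Osgin1 fell by 0.78 and 0.75. Nfat5 itself, the transcription factor of the osmotic response, did not pass (-0.41, adjusted p = 0.0815), but did without control 5, at -0.53. The surfactant list was not called (8 of 20 up and 3 down, the same adjusted over the list alone; camera adjusted p = 0.349), but its score was higher by 0.26 (exact permutation adjusted p = 0.0278), and by 0.19 without Lpl, its member with the largest change (unadjusted exact p = 0.0303). In it Ctsh rose by 0.97 and Sftpb fell by 0.62, and Sftpc did not pass (-0.26, adjusted p = 0.151), taking 1.38 ± 0.209% of control and 1.17 ± 0.166% of ALI libraries.

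The hypoxia list was not called (6 of 26 up and 7 down, the same adjusted over the list alone, camera adjusted p = 0.944). Without control 5 and ALI 2, 11 of its 26 genes rose and 7 fell, and it was still not called (camera adjusted p = 0.507). Among its members Slc2a1 and Hif1a (0.97) rose, while Vegfa and Hilpda (-1.44) fell. The NRF2 list was not called (3 of 23 up and 9 down, 5 and 9 adjusted over the list alone, camera adjusted p = 0.263). Without control 5 and ALI 2, 9 of its 23 genes rose and 9 fell (camera adjusted p = 0.827). Among its members the cystine importer Slc7a11 rose 18.9-fold and Hmox1 rose by 1.39, while the glutathione transferases Gsta3 and Gstm1 were at -1.95 and -1.64. The immediate early gene list was not called (5 of 28 up and 7 down, the same adjusted over the list alone, camera adjusted p = 0.798), with Egr2 at 2.08, Atf3 at 1.71, Fosl2 at 0.71 and Jun at -0.94. By fry without regard to direction, which most lists passed, the hypoxia, NRF2 and immediate early lists passed too (adjusted p = 2.01e-09, 4.29e-08 and 1.53e-09). The camera direction was opposite in sign to the list median in the hyperosmotic, hypoxia, NRF2, heat shock, glucocorticoid and mesothelial lists, and to the list mean alone in the ion transport, immediate early, histone, club and goblet, and oesophagus and thyroid lists, none of which was called by camera.

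Clock genes differed between the groups. Of 18 circadian genes 3 rose and 9 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.000339, and adjusted p = 0.153 with an estimated correlation). The repressor Nr1d1 fell from 324 ± 42.1 to 100.2 ± 14.7 CPM and Cry2 was at -1.13. Dbp fell by 1.80 and Arntl rose by 1.44, both chosen after their values were seen as members of opposite phase.

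Blood markers fell. Of 11 erythroid genes 7 fell and none rose, the same adjusted over the list alone (camera adjusted p = 2.59e-05, and adjusted p = 0.219 with an estimated correlation), and the haemoglobin genes took 0.714 ± 0.299% of control and 0.108 ± 0.0226% of ALI libraries (two-sided exact permutation p = 0.0021645, adjusted p = 0.00606). Of 13 platelet and megakaryocyte genes 10 fell and none rose (11 adjusted over the list alone; camera adjusted p = 0.000828, and adjusted p = 0.134 with an estimated correlation), with Nrgn at -1.22 and Ppbp at -1.44.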

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

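Each of 471 groups of 6 values (library measures, marker transcripts, list scores and named genes) was checked for a sample far from the other 5, by its gap to the nearest of them over the whole range, and 61 had one. The cut flags about 1 in 20 groups of independent normal values. Here some markers were chosen after their values were seen, genes counted in a single control (Saa4, Gp2 and Dmbt1) are flagged of necessity, and groups share samples. The 61 therefore cannot be set against chance. Control 5 was the distant sample in 32 of them and ALI 2 in 12. The tests of mitochondrial release, of a wrong label, of the clock genes and of the capillary and alveolar type 1 genes were chosen only after the results were seen; the test for brown adipose tissue was fixed before its result was seen.

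Control 5 stood above the other controls in adipose and metabolic transcripts and in some of other kinds, far above in Ucp1, Adipoq, Cox8b and Cidea. It held 2858 CPM of Ucp1, the uncoupling protein of brown fat, against at most 0.293 in the others, 269 of Adipoq, 664 of Cox8b and 729 of Cidea. It also held 314 of Fabp3, 35.4 of Ces1g, 5.10 of Slc7a11, 13.7 of Slc26a4, 3.07 of Tnf, 25.6 of Jchain and 0.150 of Slc6a12 (4 counts over all controls). Its airway transcripts Scgb1a1 (23280.3 CPM) and Cbr2 (4610 CPM) were also the highest, its Cdh5 (813 CPM) and Kit (190 CPM) the lowest, and its Trp63 was 0. Mitochondrial genes took 9.85% of its library and ribosomal protein genes 3.34%. Its log2 list scores were highest for adipose tissue (9.52), mitochondrially encoded genes (10.67), oxidative phosphorylation (9.03), ribosomal proteins (8.93), surfactant (9.20), hypoxia (6.25), NRF2 (6.38), ferroptosis (6.14), glycolysis (7.26) and lipid synthesis (7.37). Its scores were lowest for junctions (7.05), matrix (6.12), alveolar type 1 cells (8.65) and capillary endothelium (7.98).

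A candidate explanation for control 5 is brown adipose tissue carried into the sample. Of 17 further brown adipose markers counted in a control, 16 lay more than 1 log2 unit above the highest other control, among them Otop1 at 78.0 against 0.0587 CPM, Cox7a1 at 178 against 1.73 and Acaa2 at 1347 against 175; of 14 matched members of the fixed adipose list, 4 had a median of at least 1 CPM in the other 5 controls. Release of mitochondrial RNA by damaged cells is argued against, since 28 nuclear genes of oxidative phosphorylation stood a median of 3.24 log2 units above the mean of the other controls. A wrong label is argued against as well: on a scale from 0 at the mean of the other controls to 1 at the mean of the ALI samples, over the genes changed at least 2-fold without it, control 5 lay at 0.106, and the ALI samples between 0.81 and 1.13. The other 5 controls lay between -0.053 and 0.046, so control 5 was outside their range, on the side of ALI. No biological explanation within the lung was tested, and a true difference in the lung of this animal stays open.

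Clock genes differed between the groups, and 12 of 12 called members moved as a shift of phase gives, with Nr1d1, Cry2 and Dbp lower and Arntl higher. A different time of day at collection and an effect of the injury on the clock cannot be told apart, because the labels give no collection time and each group may have been collected together. Adipose tissue in control 5 and ALI 2 is argued against, since 12 of 12 stayed called in their direction without these samples.

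Capillary and alveolar type 1 transcripts were lower in ALI, which dilution by incoming leukocytes could give if all resident cell types fell alike. The capillary score fell more than the ciliated score (difference -0.79, two-sided exact permutation p = 0.0390, adjusted p = 0.0487) and more than the alveolar type 2 score (difference -1.22, exact p = 0.0021645, the smallest possible), which argues against dilution alone for the capillary genes. For alveolar type 1 genes dilution cannot be told apart from a fall of their own, since the difference from the ciliated score was -0.60 (exact p = 0.123) while that from the alveolar type 2 score was -1.02 (exact p = 0.0021645). The scaling of the libraries moves all genes of a library alike and cancels in these differences. Scaling is therefore not the whole cause of the gaps of -1.22 and -1.02 to the alveolar type 2 score. That score itself rose by 0.29 (two-sided exact permutation p = 0.00433), so both gaps hold its own change too. They cannot tell how much of the capillary and alveolar type 1 fall is due to scaling. Fewer endothelial cells and lower transcription per cell stay open and were not tested. Haemoglobin genes took 0.714 ± 0.299% of control and 0.108 ± 0.0226% of ALI libraries. Less blood RNA leaves a larger share to resident transcripts, which argues against less blood RNA as the cause of their fall.

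ALI 2 stood above the other ALI samples in transcripts of adipose and antibody-secreting cells, with 1.92 CPM of Ucp1, 59.2 of Adipoq, 3.61 of Cidea, 868 of Igkc, 218 of Igkv4-68 and 372 of Jchain. Its log2 scores were the highest of the ALI group for adipose tissue (6.13), lipid synthesis (6.66), complement (5.96), alveolar macrophages (5.91), oesophagus and thyroid (2.54) and liver (3.82). ALI 4 held 127 CPM of Xist, against at most 0.725 in any other sample, beside 106 CPM of the Y-linked Ddx3y, which lay between 87.1 and 114 CPM in all 12 samples; whether this library mixes RNA of several animals was not tested, so what it stands for as a replicate is open. It also held 136 CPM of Cxcl3 and 15.9 of Bcl2a1b, 49.1% of whose exon bases overlap another gene. ALI 3 was highest of its group in Eln (3242 CPM), Cyp2a5 (18.8) and Asgr1 (0.493), and lowest in C1qc (92.9 CPM) and in the score of sex-linked genes (4.95). ALI 1 was highest in Cxcl5 (24.4 CPM) and Arntl (13.3 CPM). Control 1 was highest in Cyp2a5 (157 CPM), Gp2 (0.487 CPM) and the basal cell score (1.37), control 2 in Saa4 (0.0619 CPM), control 3 in Dmbt1 (0.109 CPM) and control 6 in Zc3h12a (13.9 CPM) and Igkv4-68 (0.780 CPM).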

How the results depend on the processing

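Leaving out control 5 and ALI 2 together, the adipose covariate and protein-coding genes only were chosen after the results were seen. The counts of changed genes stayed within 1.5 times the reported ones in every fit at the 0.05 threshold. Leaving out each sample in turn gave 5169 to 7223 changed genes (2758 to 3791 higher, 2411 to 3432 lower), 1759 to 2025 changed at least 2-fold (1249 to 1412 higher, 510 to 661 lower) and 30 to 33 lists. DESeq2 called 6355 genes and shared 5907 of the 5922 in direction, limma-voom called 7768 and 1 surrogate variable gave 7633. At an adjusted p under 0.01, 1787 genes were lower, fewer because the threshold is stricter. With a correlation estimated per list, 11 lists stayed called, since the estimated correlation widens the test. The replicate number as a block gave 4822 genes; the numbers do not pair the samples (1 of 6 correlations over 0.1, from -0.27 to 0.27), and 1 control correlated best with its own number, a hint from the data and not the design.

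Of 154 called genes among those chosen for the text, 147 kept their call and direction in every fit that gave them an adjusted p. Some genes, Gp2 and Il6 among them, had such a value in 24 of 25 fits. The called genes that did not keep theirs were Trp63, Uty, Scnn1a, Igkv4-68, Fabp3, Cox8b and Cidea. Cidea reversed to 0.37 with limma-voom, to 0.87 without control 5 (range -7.60 to 0.87 leaving out each sample) and to 0.027 without control 5 and ALI 2, since control 5 held nearly all of its control counts. The ribosomal protein list reversed to a median of 0.26 with limma-voom, which weights samples; the cause was not tested. Over all fits, 1517 of 1632 list comparisons were the same, 45 lost a call (21 of them with an estimated correlation), 20 gained one, and 49 changed sign without being called on either side. Of 25 fits, the apoptosis list lost its call in 13, the lipid list in 9 and the dendritic cell and coagulation lists in 1 each (limma-voom), while calls were gained by glycolysis in 9, alveolar type 2 cells in 5, club and goblet cells in 2, arterial, venous and lymphatic endothelium in 2, and type I interferon and oxidative phosphorylation in 1 each. In counts simulated at the depth, spread and number of these samples, 38% of genes changed 1.5-fold were recovered. Depth was not varied, and far fewer genes were changed than in the data, so this share need not carry over.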

Other observations

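The tests of other splits of the samples below were fixed before their results were seen, and the values without control 5 and ALI 2 were chosen only after the results were seen. In the ferroptosis list 10 of 18 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.363 with an estimated correlation), Slc7a11 by 4.24 upward. In the list of apoptosis and p53 targets 11 of 24 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.0471, and adjusted p = 0.448 with an estimated correlation), with Bcl2a1b up by 2.88; the call was lost without control 5 and ALI 2 (adjusted p = 0.0602). The heat shock list was not called (5 of 19 up and 7 down, 6 and 7 adjusted over the list alone; camera adjusted p = 0.794), with Hspa8 up by 0.80. The list of the unfolded protein response was not called (6 of 25 up and 5 down, 7 and 7 adjusted over the list alone; camera adjusted p = 0.944), with Edem1 up by 0.84. The glucocorticoid list was not called (3 of 16 up and 3 down, 3 and 4 adjusted over the list alone; camera adjusted p = 0.798).

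Lipid droplet and cholesterol synthesis genes fell in 8 of 22 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.0413, and adjusted p = 0.699 with an estimated correlation), with the synthesis enzyme Lss at -0.86; the call was lost without control 5 and ALI 2 (adjusted p = 0.221), and its score did not pass the test (exact permutation adjusted p = 0.673). The glycolysis list was not called (4 of 16 up and 1 down, the same adjusted over the list alone; camera adjusted p = 0.0751), with the lactate exporter Slc16a3 up by 2.27, but without control 5 and ALI 2 13 rose and 1 fell (adjusted p = 4.07e-05). Of 28 nuclear genes of oxidative phosphorylation edgeR called 0, and 0 at an unadjusted p under 0.05, DESeq2 0 and limma-voom 3, the same 0 adjusted over the list alone (median -0.87, camera adjusted p = 0.252), and without control 5 and ALI 2 11 rose (median 0.18). Of 12 mitochondrially encoded genes edgeR, DESeq2 and limma-voom each called 0, and edgeR 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.86, camera adjusted p = 0.452; median 0.13 without both). Of 41 ribosomal protein genes edgeR called 0, and 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, DESeq2 0 and limma-voom 19 (camera adjusted p = 0.890), and without control 5 and ALI 2 13 rose. Of 5 replication-dependent histone genes 1 rose, the same adjusted over the list alone (camera adjusted p = 0.708).

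The lists for tissues that dissection can carry over were not called. Of 8 adipose genes 2 fell, Cox8b at -7.50 and Cidea at -6.76, and 0 adjusted over the list alone (camera adjusted p = 0.666), both set by control 5: without it Cox8b was at -0.82, no longer called, and Cidea at 0.87, while without control 5 and ALI 2 Cox8b was at -1.40 and called. The heart muscle list had 2 of 13 lower, the same adjusted over the list alone (camera adjusted p = 0.520), Actc1 being at -1.05. The skeletal muscle list had 1 of 7 lower and 0 adjusted over the list alone (camera adjusted p = 0.666), and that of thymus and lymph node 1 of 6 lower, the same adjusted over the list alone (camera adjusted p = 0.666), namely Cd8b1. The oesophagus and thyroid list had 1 of 5 higher, Slc26a4 at 3.56, and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.944). Mesothelial genes fell in 2 of 11 cases, the same adjusted over the list alone (camera adjusted p = 0.684), Igfbp6 at -1.79. Of 2 liver genes edgeR, DESeq2 and limma-voom called 0, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and of 4 sex-linked genes 1 rose, Uty at 0.27 (edgeR adjusted p = 0.0364; the call was lost on leaving out control 1, 2, 3 or 4 or ALI 1, 3, 4 or 5), the same adjusted over the list alone; both lists were too small to test. The ribosomal RNA locus CT010467.1 took 0.108 ± 0.0215% of control and 0.273 ± 0.177% of ALI counts (n = 6 each, two-sided exact permutation p = 0.0130), and up to 0.547% in ALI 5.

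Of 462 splits of the 12 samples into 6 and 6, 100 were drawn, the real one included. For the number of changed genes, only the real split, 1 of the 100, gave as many (5922, the highest other split 1126). The same held for those changed at least 2-fold (1894, the highest other 453). A random grouping is therefore unlikely to give these counts, though 1 of 100 is the smallest share these splits allow. A batch or collection time shared within a group would not be detected by these splits. For the number of lists called, 37 of the 100 gave as many as the 32 reported. The highest other split gave 42 and the median of the others was 27. Splits with unequal numbers of controls on each side keep part of the group difference. Among those with equal numbers the highest gave 23 lists (controls 1, 2 and 4 with ALI 1, 3 and 6). The 37 of 100 therefore cannot decide whether the number of lists called is beyond chance. The drawn splits with equal numbers, in which the group difference cancels, all gave fewer than the 32 reported. Camera at the preset correlation still called from 6 to 23 lists in them, with 0 genes called. Its adjusted p alone therefore cannot part a list changed between the groups from one whose members move together.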
